A study of Drosophila melanogaster with 2 samples.

How the data were processed

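Chromatin immunoprecipitation with sequencing (ChIP-seq) had been carried out with an anti-GFP antibody on whole prepupae of Drosophila melanogaster, males and females pooled. Per the labels, the flies carried a transgene for the protein of locus CG6854 with GFP at its C terminus, the target was CTPsyn, chromatin was sheared by sonication, and the 2 libraries were biological replicates numbered 2 and 3. They form 1 group, so no comparison between groups was made. The reference annotation lists CG6854 as an older name of both Ctps, the gene of CTP synthase, and CG45071, an overlapping gene for an uncharacterized protein, so the name alone leaves open which product carried the tag. Libraries of control DNA were not analysed here.

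The authors deposited narrowPeak lists on builds dm6 and dm3. Per the notes deposited with the files, each replicate list and the pooled list were called with relaxed settings against a control alignment, the pooled list on the alignments of both replicates together. A further list held the peaks that passed the irreproducible discovery rate (IDR) threshold, derived from the 3 relaxed lists. The aligner and the peak caller are not given in the sources used here. The signal value of a peak is a score that the authors deposited with each peak; its scale is not stated and it was used to describe, rank and filter peaks within a list. The deposited −log10 q-value was at its maximum of 4.18 in all 5703 peaks of the IDR list and could not rank them. Depth per library is unknown from these lists, and since each relaxed list ends at 30000 peaks, the number of peaks does not stand in for it. Intervals cover counting error only.

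All tests used the dm6 lists on chromosome arms X, 2L, 2R, 3L, 3R and chromosome 4, and every peak on these arms lay within their lengths. The replicate 2 list also held 17 mitochondrial summits and 1 summit on Y, which were not tested. The annotation was Ensembl release 115, with 18164 genes other than transposable elements and 23581 distinct start sites on these arms. A promoter was the 500 bp on either side of a start site. Other summits were assigned, in this order, to 5′ UTR, coding exon, 3′ UTR, intron or intergenic sequence. Shares were compared with 1000 random placements of the same number of summits on the same arm in a two-sided permutation test, whose smallest possible p is 0.002. The share of summits on X was compared with the X share of start sites on the 5 large arms in a two-sided exact binomial test. Signal inside and outside promoters was compared by a difference of medians with 100000 permutations. A protein-coding gene counted as bound with a summit in any of its promoters. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and transfer RNA (tRNA), snRNA, snoRNA and rRNA genes with random placements. Motifs were sought on both strands in 101 bp at the summit and in 101 bp centred 500 bp away, on a side drawn at random, and compared by two-sided exact McNemar tests; ratios of discordant pairs carry 0.5 added to each count. Benjamini-Hochberg adjustment was applied over the 28 gene lists, 4 RNA classes, 21 motifs and 6 location classes, with a threshold of 0.05. Shares carry 95% Wilson intervals.

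The tests, lists, motifs and alternatives were chosen before the data were examined, except where stated. Named are the tagged gene, the closest gene within 1000 bp of each of the 20 strongest peaks, up to 4 bound members with the strongest promoter peaks in each list past the threshold, all bound members of lists with 1 to 5 of them, and the 3 peaks whose rank differed most between replicates. The lists name 1611 symbols or pattern matches, of which 1601 were found. Alternatives were promoter windows of 250 and 1000 bp, the stronger part of the IDR list (2851 peaks), as many peaks from each replicate alone or from the pooled list, other rules of overlap, placement and background, and other motif controls. Chosen after seeing the data were 1 start site per gene, the histone list without near-identical copies or without 3 genes that are no histones, 8 other lists without genes that matched by symbol alone, lists without genes that start within 1000 bp of a ribosomal protein gene, shares among summits outside promoters, and the tagged locus without its strongest peaks. Protein sequences were searched against the 13945 annotated protein-coding genes with blastp at E = 1e-05.

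The tests were run on simulated data. With promoter peaks planted to a share of 48.2% among 5703 peaks, 48.3% was recovered, and 1 of 100 random peak lists passed p = 0.05 in the permutation test. These random lists were placed uniformly, as in the test, so this rate does not cover clustered summits. An odds ratio of 4 planted in a list was recovered as 4.38 among 13945 genes, and 0 of 100 random lists passed the adjusted threshold. GAGA motifs planted in 9.75% of 5703 windows were recovered in 9.63%, and 0 of the 20 motifs not planted passed. Work was done in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9 and Biopython 1.88, and with BLAST 2.17.0.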

Results

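Binding of a GFP fusion from locus CG6854 was mapped by ChIP-seq in whole prepupae, the stage at the onset of metamorphosis, in 2 biological replicates of 1 group. The target named in the labels is CTP synthase (Ctps), the enzyme that makes CTP from UTP. The IDR list on dm6 held 5703 summits in 5652 regions, with a median width of 430 bp. Signal values, the authors' score per peak, had a median of 200.1 and ran from 136.3 to 2488. The list on dm3 held 5705 summits with a median signal of 198.7. The IDR summits were the 5703 strongest of the 30000 in the pooled list.

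The strongest peak lay at the start of Ugalt, a UDP-galactose transporter, at X:2703688-2704064, with a signal of 2488. Peaks also lay 698 bp from the nearest start site of Bcat (X:13395957-13396442, signal 2258) and in promoters of ACC, the acetyl-CoA carboxylase of fatty acid synthesis (2R:7983920-7984547, signal 2133), and yip2 (2L:9915074-9915689, signal 2016). The chaperone gene Hsp83 had a promoter peak at 3L:3192886-3193299 with a signal of 1930. Other promoters among the 20 strongest were those of CG14100 (signal 2059), PNPase (signal 1792), CenG1A (signal 1767), CG1888 (signal 1730) and CG18549 (signal 1647). The peak of CenG1A is also a promoter peak of mRpS23. Some of the strongest peaks had no protein-coding start site within 1000 bp. These were an intronic peak of dnr1 at 2R:22569683-22570501 (signal 2460), an intergenic peak at X:1398918-1399915 (signal 2406), intronic peaks in CG11050 (2L:6612400-6612984, signal 1790), ush (2L:480888-481308, signal 1771) and CG32772 (X:4910013-4910767, signal 1642), and an intergenic peak at 3L:3246163-3246901 (signal 1607). The remaining 4 of the 20 strongest lay within Ctps.

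Replicate signals were compared at matched summits. Ugalt had a signal of 1160 in replicate 2 and 1337 in replicate 3, and Hsp83 had 962.5 and 981.4. Of the IDR summits, 95.4% (95% interval 94.8 to 95.9) lay within 100 bp of a replicate 2 summit and 95.9% (95.4 to 96.4) of a replicate 3 summit. As the IDR list was derived from these lists, high shares were built in and do not measure agreement. Across the 5217 summits matched in both, Spearman's rho was 0.551 and Pearson's r of log2 signal was 0.652. These summits are not independent replicates and had been selected for reproducibility. Of the 5703 strongest summits of replicate 2, 62.4% (61.1 to 63.6) were among the 5703 strongest of replicate 3, against a mean of 0.858% in 100 random placements. Ranks differed most at KrT95D (3R:24031381-24031524, promoter), with a signal of 201.8 in replicate 2 and 45.5 in replicate 3, at miple2 (3L:271525-271816, promoter), with 232.1 and 59.8, and at an intron of Fas3 (2L:18327767-18327983), with 45.1 and 247.1.

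**Figure D1:**
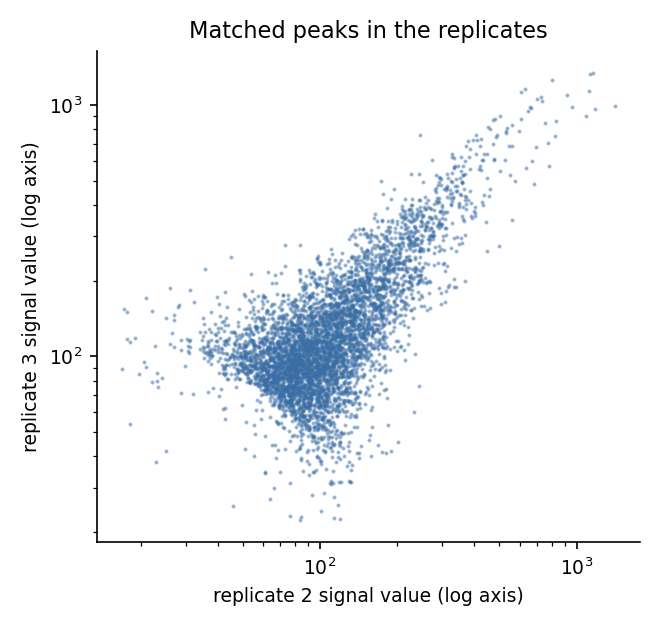
Signal value of each of the 5217 matched peaks in replicate 2 (x axis) and replicate 3 (y axis), both on log axes without a unit, 1 point per peak. The points spread around a rising band, with a Spearman's rho of 0.551.

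Promoters held 51.4% of the IDR summits (95% interval 50.1 to 52.7; 2930 of 5703), 3.78 times the 13.6% of random placements. The strongest 5703 summits of the replicates gave 51.3% ± 3.55 (SD, n = 2). Coding exons outside promoters held 0.544% against 13.7% at random, and 3′ UTRs held 0.754% against 4.39%. Introns held 34.1% against 40.1%, and intergenic sequence held 12.2% against 27.5%. Each of these 5 classes differed from random placement (two-sided permutation test, adjusted p = 0.0024, the smallest the placements can give here). The 5′ UTR share, 0.999% against 0.772%, did not pass (permutation test, adjusted p = 0.0759), and did pass with a promoter window of 250 bp (2.54%) and in replicate 3 alone (1.16%; permutation test, adjusted p = 0.002 in both). As the shares add to 100%, the promoter excess alone lowers the others. Among the 2773 summits outside promoters, set after the values were seen against random positions outside promoters, introns held more than at random (70.1% against 46.4%), as did 5′ UTRs (2.06% against 0.887%). Coding exons (1.12% against 15.8%), 3′ UTRs (1.55% against 5.06%) and intergenic sequence (25.2% against 31.8%) held fewer (permutation test, adjusted p = 0.002 in each class). The median distance to a start site was 442 bp, and 15.2% of summits lay over 5000 bp from any.

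**Figure D2:**
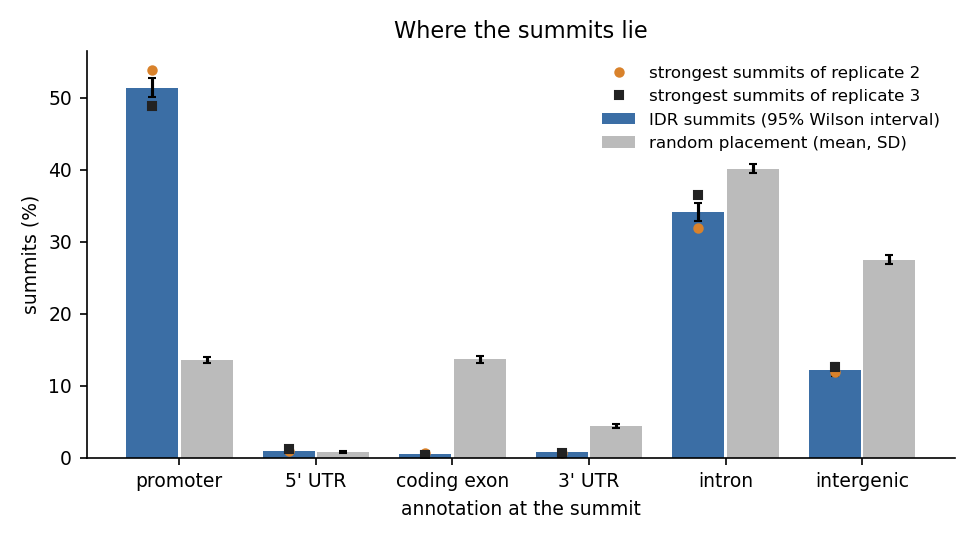
Share of summits (%, y axis) in 6 annotation classes (x axis) for the IDR list with 95% Wilson intervals, for random placement with its SD, and for the strongest summits of each replicate as points. Promoters held 51.4% of the summits against 13.6% at random, while coding exons held 0.544% against 13.7%.

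Promoter peaks were stronger, with a median signal of 204.9 against 194.6 elsewhere, a difference of 10.3 (permutation test, two-sided, p = 7e-05; 2930 and 2773 summits). Among the stronger 2851 peaks this difference was not found, at -0.0283 (permutation p = 0.997).

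Peak density ran from 39.0 summits per Mb on X to 47.2 on 2R among the large arms, and was 15.6 per Mb on chromosome 4, with 21 summits. The X chromosome held 16.2% of summits (95% interval 15.2 to 17.1; 918 of 5682) against 16.7% of start sites (exact binomial p = 0.278). In replicate 3 alone the share was 15.4% (exact binomial p = 0.00648), in replicate 2 alone 17.1% (exact binomial p = 0.445), and against the X share of arm length, 17.8%, p was 0.0014 by the same exact test.

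Ribosomal protein genes were bound far more often than other genes. Of 93 genes in the list of cytoplasmic ribosomal proteins, 78 had a promoter summit (83.9%), against 19.97% of all 13945 protein-coding genes, an odds ratio of 21.4 (95% interval 12.3 to 37.3; Fisher's exact test, adjusted p = 9.94e-39). A bound gene of the list, qm (quemao), matched by symbol and encodes no ribosomal protein, and without it 77 of 92 were bound (odds ratio 21.1). The strongest promoter peaks were at RpS4 (signal 935), RpL24 (signal 852.7), RpS27 (signal 840.4) and RpS10b (signal 795.4). Translation factors were bound at 23 of 54 genes (odds ratio 2.99, exact test, adjusted p = 0.000585), led by eIF4EHP (signal 845.9), eEF1gamma (signal 789.6), eIF6 (signal 645.4) and eIF1 (signal 502.7).

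Stress, hormone and chaperone genes were also bound more often. Stress and redox genes were bound at 20 of 28 (odds ratio 10.1, exact test, adjusted p = 3.94e-08), with the strongest promoter peaks at Cat, encoding catalase (signal 1376), the phosphatase gene puc (signal 1036), Sesn (signal 578.3) and Sod1 (signal 450.5). The ecdysone response list had 22 of 34 bound (odds ratio 7.4, exact test, adjusted p = 9.4e-08), including the nuclear receptor genes Eip75B (signal 564.7), ftz-f1 (signal 496.1) and Hr3 (signal 479.3), and Ldh, encoding lactate dehydrogenase (signal 606.8). With 1 start site per gene, an alternative chosen after the values were seen, the odds ratio of this list was 3.32 and still passed. Heat shock and chaperone genes were bound at 19 of 41 (odds ratio 3.48, exact test, adjusted p = 0.000384), with Hsp83 followed by Hsp27 (signal 1405), DnaJ-1 (signal 328.2) and Hsp26 (signal 310.9).

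Lists of phospholipid, nucleotide and glycolytic genes were bound more often too. The phospholipid synthesis list, of which only some members use CTP, was bound at 9 of 14 (odds ratio 7.23, exact test, adjusted p = 0.000874), with peaks at Lpin, encoding the phosphatidate phosphatase lipin (signal 1166), eas, the ethanolamine kinase gene (signal 402.1), CG33116 (signal 264.7) and Pcyt1 (signal 264). Its bound gene PEK encodes a kinase of translation control, and without it 8 of 13 were bound (odds ratio 6.43, exact test, adjusted p = 0.00286). Without replicate 2 the odds ratio of the full list was 4.26. Nucleotide synthesis genes were bound at 13 of 30 (odds ratio 3.07, exact test, adjusted p = 0.00856), with Ctps itself (signal 2008), l(2)k01209 (signal 614.4), Prps (signal 460.1) and ras, the fly IMP dehydrogenase gene (signal 240.1). The Ctps peak lies at the tagged locus, 103 bp from the start of CG45071, where binding and extra DNA copies could not be told apart. Glycolytic genes were bound at 9 of 17 (odds ratio 4.52, exact test, adjusted p = 0.00547), with Gapdh2 (signal 1076), Eno (signal 851.4), Ldh and Hex-A (signal 584.5). Among the stronger 2851 peaks, nucleotide synthesis (odds ratio 1.6, adjusted p = 0.552) and glycolysis (odds ratio 3.33, adjusted p = 0.0671) no longer passed Fisher's exact test.

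Chromatin and insulator protein genes were bound at 22 of 52 (odds ratio 2.95, exact test, adjusted p = 0.000821), with Chro (signal 1493), ph-p (signal 921), Dref (signal 664) and Cp190 (signal 524.5). The peak of Dref is also that of RpL13, and the peak of eIF1 that of RpL28. Without genes that start within 1000 bp of a ribosomal protein gene, an alternative chosen after the values were seen, the chromatin list (odds ratio 2.86) and the translation factors (odds ratio 2.9) still passed the exact test. Fat body genes were bound at 11 of 26 (odds ratio 2.95, exact test, adjusted p = 0.0202), with ACC, Glyp, the glycogen phosphorylase gene (signal 658.5), Ilp6 (signal 379.8) and mdy (signal 322). The fat body list did not pass in replicate 2 alone (odds ratio 2.43, Fisher's exact test, adjusted p = 0.0771), among the stronger peaks (2.4, adjusted p = 0.108) and with 1 start site per gene (2.5, adjusted p = 0.0636).

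Chemoreceptor, cuticle, seminal fluid, cytochrome P450 and histone lists were bound less often than other genes. Of 231 chemoreceptor and odorant-binding protein genes 1 was bound, Obp83g (signal 140), an odds ratio of 0.0171 (exact test, adjusted p = 4.61e-20). Of 123 cuticle protein genes 0 were bound (exact test, adjusted p = 1.62e-11). Seminal fluid and testis genes were bound at 1 of 81, Mst85C (signal 143.6; exact test, adjusted p = 1.75e-06), and the cytochrome P450 list at 4 of 85 (odds ratio 0.197, adjusted p = 0.000355), which were Cyp6u1 (signal 336.2), Cyp6a17 (signal 244.8), Cyp6v1 (signal 182.3) and Cyp1 (signal 146.6). Cyp1 and the unbound Cyp40 encode cyclophilins and matched by symbol, and without them 3 of 83 were bound (odds ratio 0.149, Fisher's exact test, adjusted p = 8.44e-05). The histone list, taken by symbol, was bound at 4 of 118 (exact test, adjusted p = 8.67e-07). These 4 were His3.3B (signal 156.2), His4r (signal 139), HisCl1 (signal 278) and HisT (signal 156.3). HisCl1 encodes a histamine-gated chloride channel and HisT a histamine transporter, and with HisRS they are 3 genes that matched by symbol and are no histones. Without these, a step chosen after the values were seen, 2 genes were bound, an odds ratio of 0.0703 (Fisher's exact p = 5.37e-09). Reads from near-identical histone copies cannot be assigned to a copy, and of the 4 histone genes without such copies 2 were bound, too few to pass (Fisher's exact p = 0.18). Mst85C, Cyp1 and His4r had no promoter summit among the strongest peaks of replicate 3 alone. Cyp6a17 and HisT had none among those of replicate 2 alone.

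The other 13 lists did not pass the threshold. Larval glue and salivary gland genes had 1 of 25 bound, fkh (signal 244.6; exact test, adjusted p = 0.078). This list passed in replicate 2 alone, at an odds ratio of 0.076 (Fisher's exact test, adjusted p = 0.00957), and with a window of 1000 bp, at 0.136 (adjusted p = 0.0298). Circadian clock genes had 5 of 13 bound (exact test, adjusted p = 0.229), with sgg (signal 734.2), vri (signal 336.7), cyc (signal 277.6), cry (signal 181.5) and Pdp1 (signal 164.4). Blood cell genes had 4 of 20 bound (exact test, adjusted p = 1), with msn (signal 371.7), ush (signal 336.1), crq (signal 146.5) and lz (signal 146.2). Among the strongest peaks of replicate 2 alone, fkh and cry had no promoter summit. Among those of replicate 3 alone, crq and lz had none. The chorion and vitelline list had 1 of 20 bound (exact test, adjusted p = 0.229), and that gene, Cp190, encodes an insulator protein that matched the list by symbol alone. Autophagy and cell death genes were bound at 12 of 38 (adjusted p = 0.165), and in replicate 2 alone this list passed (Fisher's exact test, adjusted p = 0.00159). Oxidative phosphorylation was bound at 13 of 90 (exact test, adjusted p = 0.326), neuronal genes at 6 of 43 (adjusted p = 0.592), the proteasome at 8 of 48 (adjusted p = 0.874) and immune effectors at 8 of 47 (adjusted p = 0.874). DNA replication and cell cycle was bound at 9 of 43 (exact test, adjusted p = 0.974), Hox and patterning at 12 of 58 (adjusted p = 0.974), mitochondrial ribosomal proteins at 14 of 73 (adjusted p = 1) and muscle at 6 of 33 (adjusted p = 1). With 1 gene per peak, mitochondrial ribosomal proteins passed as less often bound, at an odds ratio of 0.295 (Fisher's exact test, adjusted p = 0.0176), and oxidative phosphorylation did so among the stronger peaks, at 0.274 (adjusted p = 0.0363), and with the relaxed background, at 0.371 (adjusted p = 0.00723).

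Set against the 6712 genes with a relaxed pooled summit at a promoter, 4 of the 10 enriched lists passed, namely ribosomal proteins (odds ratio 22.6), stress and redox (odds ratio 5.67), ecdysone response (odds ratio 3.9) and heat shock and chaperones (odds ratio 2.99). The other 6 did not pass, at odds ratios of 3.18 for phospholipid synthesis, 2.63 for nucleotide synthesis, 2.54 for glycolysis, 2.04 for translation factors, 1.73 for fat body and 1.24 for chromatin and insulator proteins. Of the 5 depleted lists only 7 to 18 genes had a relaxed summit and none passed, although odds ratios stayed low for cuticle (0.0938), chemoreceptors (0.128), seminal fluid (0.176) and cytochrome P450 (0.402). Only histones turned, at 1.88. The nucleotide synthesis (Tk, udd), glycolysis (Pgam5), fat body (mio) and seminal fluid (Acp65Aa) lists also held genes that matched by symbol alone, and against all genes these lists passed without them (odds ratios 3.48, 5.17, 2.68 and 0.0504). These exclusions and those above were chosen after the values were seen.

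**Figure D3:**
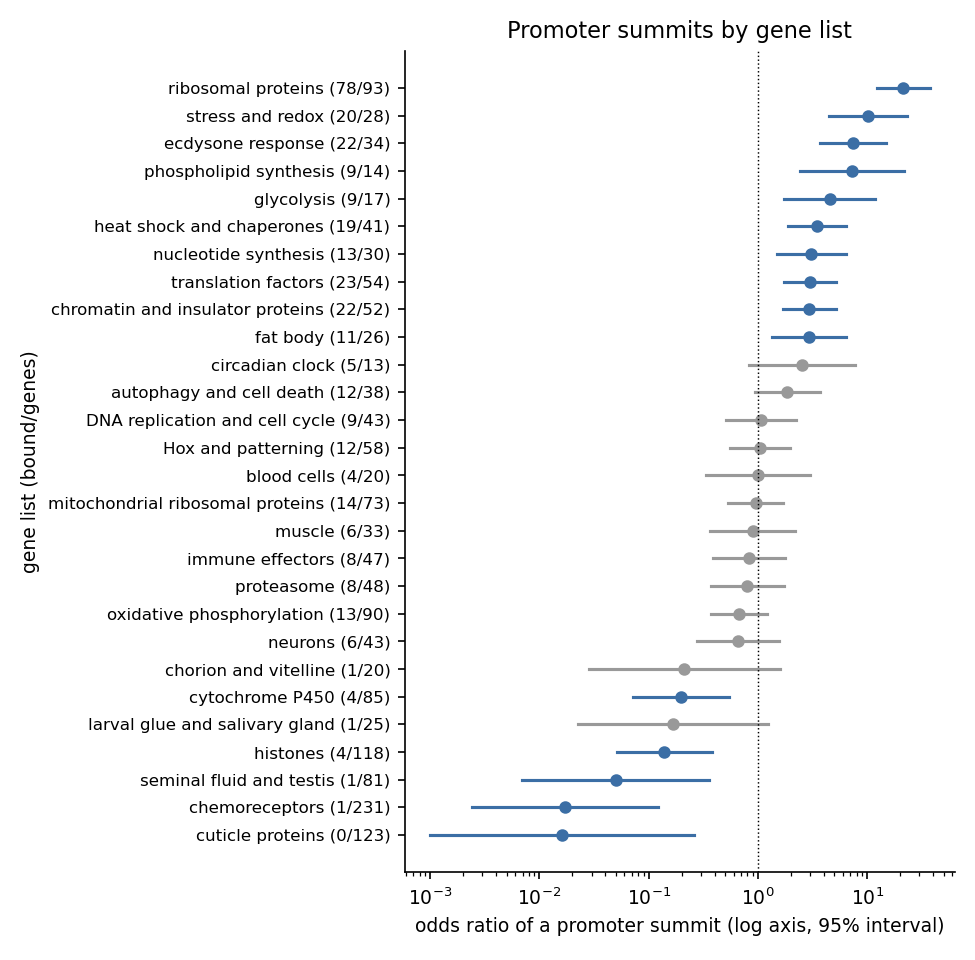
Odds ratio of a promoter summit (x axis, log scale, 95% interval) for each of 28 gene lists (y axis, bound and total genes), blue where adjusted p was under 0.05 and grey elsewhere. Ribosomal proteins stand highest at 21.4 and cuticle proteins lowest, with 0 of 123 bound.

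Transfer RNA genes had IDR summits nearby more often than random placement. Of 290 tRNA genes 59 (20.3%) lay within 500 bp of a summit, against 4.62% at random (permutation test, adjusted p = 0.00799). They lay at 39 distinct summits, of which 11 were also at a protein-coding promoter. The share was near the 19.97% of all protein-coding genes that were bound, so it does not set tRNA genes apart from these. The shares were 9.29% for snoRNA genes (adjusted p = 0.12) and 9.38% for 32 snRNA genes (adjusted p = 0.426) in the same permutation test. Of 99 rRNA genes 0 had a summit nearby, against 5.5% at random (permutation test, adjusted p = 0.352). As 0 is the lowest share possible, this test could not have called them depleted. For snoRNA genes the call was made in replicate 2 alone, at 11.2% (permutation test, adjusted p = 0.032), and with a window of 1000 bp, at 22.3% (adjusted p = 0.004).

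GA repeats were more frequent at summits than beside them, though in a small share of the windows. The GAGA motif, GAGAGAG, was present in 6.21% of summit windows and 2.17% of flanking windows (354 and 124 of 5703; exact McNemar test, adjusted p = 6.11e-26), with 6.61% in replicate 2 and 5.35% in replicate 3. Also more frequent at summits were the Ohler E-box (4.07% against 2.49%, exact test, adjusted p = 1.45e-05), the Initiator (11.8% against 9.03%, adjusted p = 1.16e-05), the CA repeat (2.44% against 1.47%, adjusted p = 0.000902) and the ZIPIC motif (0.473% against 0.14%, adjusted p = 0.00657). The DPE consensus, RGWYVT, was less frequent (47.2% against 52.3%, exact test, adjusted p = 6.62e-07), as was the TATA box (3.89% against 4.94%, adjusted p = 0.0214). Matches were counted anywhere in a window, whatever their distance from a start site, so they do not show working core promoter elements. The other 14 motifs did not pass, among them DRE (exact test, adjusted p = 0.605), Motif 1 (adjusted p = 0.12), CTCF (adjusted p = 0.109), the E-box (adjusted p = 0.0684), the core site of the ecdysone response element (adjusted p = 0.12) and the heat shock element (adjusted p = 0.081). Against unbound start sites at the same distance, the Initiator (odds ratio 1.09, Fisher's exact test, adjusted p = 0.507), the Ohler E-box (1.16, adjusted p = 0.507) and ZIPIC (2.23, adjusted p = 0.182) did not pass. Among the stronger peaks the Ohler E-box, ZIPIC, the CA repeat and the TATA box did not pass. Motif 1 passed as more frequent in wider windows (ratio 3.76, exact test, adjusted p = 5.34e-09) and against the weakest pooled peaks (3.68, adjusted p = 0.011). The ecdysone response element core passed as less frequent against unbound start sites (0.607, exact test, adjusted p = 0.00341) and in each replicate alone (0.695 and 0.685). In replicate 2 alone Motif 7 (1.64, exact test, adjusted p = 0.0309) and poly A (1.38, adjusted p = 0.0113) passed as more frequent. Against the weakest peaks of the pooled list the TATA box was more frequent at summits, at an odds ratio of 1.5 (Fisher's exact test, adjusted p = 0.00122). With the same peaks and another draw of flanking sides the TATA box did not pass (exact McNemar test, adjusted p = 0.147), and without replicate 2 neither it (adjusted p = 0.473) nor the Ohler E-box (adjusted p = 0.0622) did.

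**Figure D4:**
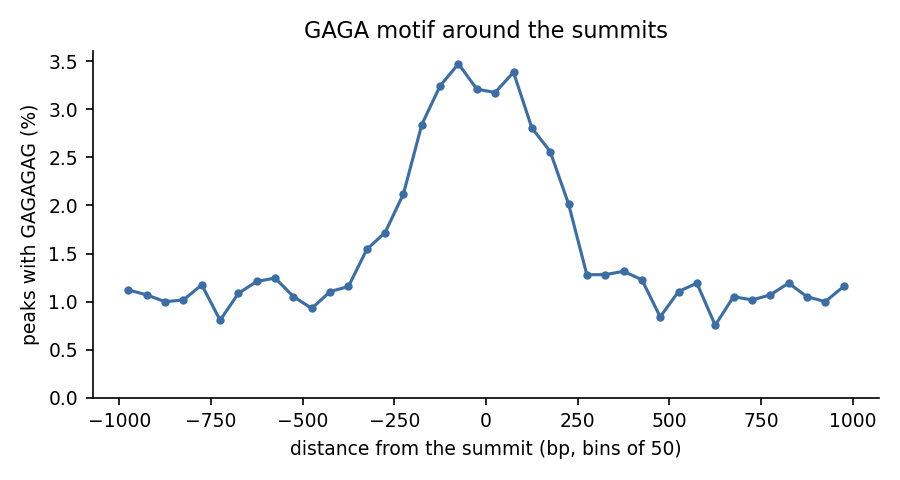
Share of the 5703 IDR peaks (%, y axis) with GAGAGAG on either strand in bins of 50 bp by distance from the summit (bp, x axis). The share is highest around the summit, at 3.17% to 3.47% in the bins centred from -125 to 75 bp, with no clear offset to either side.

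The tagged locus carried a dense group of strong peaks. Ctps lies at 3L:15097914-15113003 and overlaps CG45071 at 3L:15105882-15110730, both on the plus strand. Within the Ctps gene, 7 summits with signals from 1043 to 2008 lay in 4 regions between 15101173 and 15108761. The strongest, at 15105779, lay 103 bp from the start of CG45071, which is also an alternative start of Ctps, with a signal of 1091 in replicate 2 and 902.5 in replicate 3. The others were in introns of Ctps, except a summit at 15101804 (signal 1671) beside the start of the pseudogene CR43972. The region from 15103899 to 15106275, 2377 bp wide, was the widest of the list, and the widest outside this group was 1552 bp. The group ended before the coding start of CG45071 at 15108805. Downstream of it within Ctps, where the exons for the C terminus lie, the pooled relaxed list held 1 summit, with a signal of 57.0. Within 50 kb of the middle of Ctps there were 13 IDR summits, a number reached or passed at 7.01% of protein-coding genes, whose median was 5. Within 20 kb there were 10, reached or passed at 1.28% of genes, where the median was 2. Within 50 kb, replicate 2 alone had 16, reached or passed at 3.08% of genes, and replicate 3 alone 14, at 5.0%. The relaxed pooled list held 31, against a median of 27, and 42.6% of genes had as many. Without the 7 strong summits the IDR list held 6 within 50 kb, reached or passed at 43.7% of genes.

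**Figure D5:**
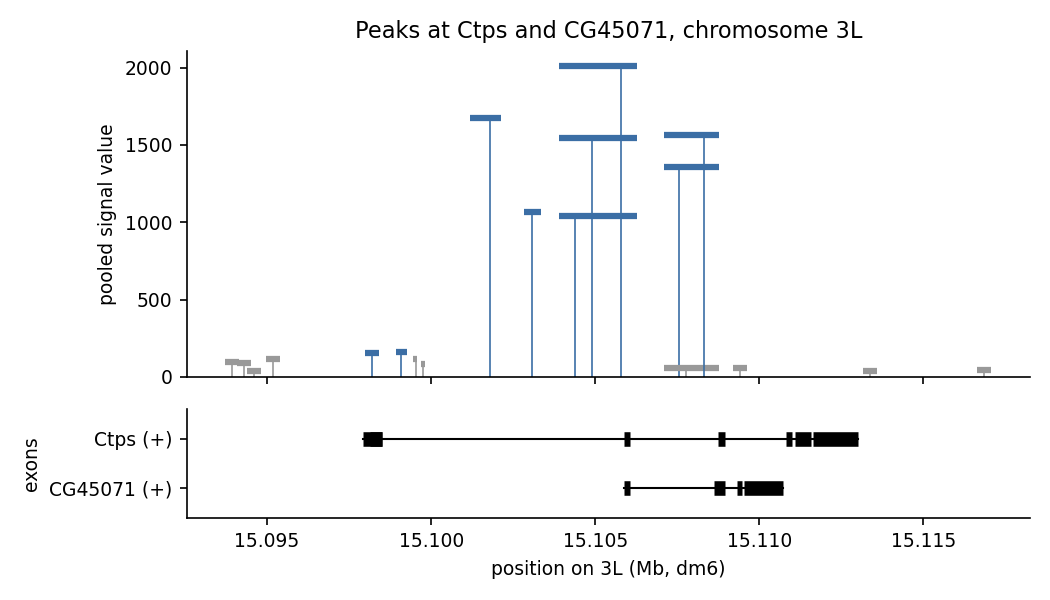
Peaks of the pooled list at Ctps and CG45071 on 3L (x axis, Mb, dm6) drawn as bars at their signal value (y axis), with a line at the summit, blue for IDR summits and grey for others, above the exons of both genes. The 7 summits with signals of 1043 or more lie upstream of the exons at the 3′ end.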

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

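The replicate 2 list on dm6 held 17 summits on the mitochondrial genome, a sequence outside the comparisons above. They stood out because a count of 0 allows no more than 3, a bound that treats summits as independent, which neighbouring summits are not. They included the 10 strongest peaks of that list, up to a signal of 3599, and covered 33.4% of the mitochondrial sequence. The replicate 2 list on dm3 held 5, up to a signal of 407.5. The replicate 3 list and the pooled list held 0 on both builds. As the pooled list was called on the alignments of both replicates, its count does not follow from that of replicate 3. The cause was not tested.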

How the results depend on the processing

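Alternatives with 1 start site per gene, without near-identical histone copies, without genes that matched a list by symbol alone, without genes that start beside a ribosomal protein gene, among summits outside promoters and without the strongest peaks of the tagged locus were chosen after seeing the data. Over 136 results and 784 alternatives, 567 values kept their direction and side of the threshold or stayed within their spread, 26 lost the threshold, 27 gained it, 112 moved and 52 changed direction. As many peaks from the pooled list were the IDR peaks themselves, so that this alternative changes only the draw of flanking sides. Outside the motifs its values were fixed in advance, and they add to the 567 without testing anything. The promoter share passed in each alternative run. The cause was not tested for any change below unless the alternative's construction gives it. Depth is unknown and sets no limit that can be stated.

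The share of replicate 2 summits among the strongest of replicate 3 was 72.3% within 250 bp, 73.4% for any overlap, 58.4% for a reciprocal overlap of 50% and 64.9% for lists of 2851 peaks. The X share was 16.2% against arm length, which passed, and 15.4% to 17.1% with a replicate left out. The promoter signal difference was -0.0283 among the stronger peaks. With only genes that had a relaxed peak as background, 5 gene lists passed. Of 68 named genes, 5 were not bound without replicate 2 and 4 without replicate 3. Among the stronger peaks 11 of them were not bound. RNA classes passing were 2 (tRNA and snoRNA) with a window of 1000 bp and 1 to 2 with a replicate left out. Motifs passing were 3 among the stronger peaks (2 more and 1 less frequent) and 11 in the wider windows (7 more and 4 less frequent). Some of those gained in the wider windows are not named here. Without its strongest peaks, the tagged locus had 6 summits. The 5′ UTR share fell below random placement, at 0.737% among the stronger peaks and 0.298% with a window of 1000 bp, and passed above it at 2.54% with a window of 250 bp and 1.16% without replicate 2. The intron share, below random placement over all summits, was above it among summits outside promoters, at 70.1%, since the promoter excess no longer lowers it.

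Among gene lists, only the list taken as histones by symbol turned from a call, with odds ratios of 1.88 with the relaxed background and 5.35 without near-identical copies. The 5.35 does not measure histones, since 3 of its 7 genes are none, and without these it was 4.01 and did not pass (Fisher's exact p = 0.18). Other odds ratios that crossed 1 had not passed before. With the relaxed background they were 0.486 for DNA replication, 0.845 for Hox, 0.94 for autophagy, 1.03 for immune effectors, 1.41 for chorion and 2.12 for muscle. Among the stronger peaks they were 0.818 for DNA replication, 0.886 for blood cells, 1.12 for mitochondrial ribosomal proteins, 1.17 for immune effectors and 1.43 for muscle. With 1 gene per peak they were 0.828 for DNA replication, 0.901 for blood cells and 1.14 for muscle, and with 1 start site per gene 0.832 for blood cells, 0.866 for Hox, 0.917 for DNA replication and 1.12 for mitochondrial ribosomal proteins. A window of 250 bp gave 0.81 for DNA replication and 0.882 for blood cells, and one of 1000 bp gave 0.816 for blood cells, 0.851 for Hox and 1.07 for mitochondrial ribosomal proteins. Without genes that start beside a ribosomal protein gene, blood cells had 0.763. With a replicate left out, blood cells ranged from 0.472 to 0.971 and Hox from 0.713 to 1.11.

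Among motifs, the TATA box turned to a ratio of 1.5 against the weakest pooled peaks, where Motif 6 had 2.0 and poly A 0.946. Against unbound start sites the ratios were 0.708 for DRE, 0.800 for poly A, 0.825 for Motif 1 and 1.4 for Motif 6. Motif 6 had 1.86 among the stronger peaks, and the BEAF core pair 1.12 in the wider windows. With a replicate left out the ranges were 1.06 to 1.15 for AP-1, 1.47 to 1.53 for Motif 6, 0.818 to 1 for Su(Hw), 0.915 to 1.15 for DRE, 0.846 to 1.08 for the E-box and 1 to 3.67 for the BEAF core pair.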

Other observations

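Chosen after the results were seen were the tests of genes that most cells use, of extra gene copies and of the CG45071 protein; those of tRNA genes, of start sites per gene and of promoter base content were set before their results were known.

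The genes with the most IDR summits inside them, counted after the data were seen and without a test, were sbb (26 summits in 79.1 kb), Eip75B (25 in 113.7 kb), jing (21 in 119.8 kb), shn (19 in 58.3 kb), and Tet, kirre and psq (17 each). EcR, the ecdysone receptor gene, held 16. Among all 32888 sequences of 8 bases tested, 106 were more frequent at summits and 10 less frequent (exact McNemar test, adjusted p under 0.05). Of the 106, 62 held GAGAG, AGAGA, AGAGC, GAGCG or GCGAG on either strand, a class defined after seeing them, led by AGAGAGCG (176 summit and 46 flanking windows, exact test, adjusted p = 5.77e-15).

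Ribosomal, stress and ecdysone genes were bound more often than other genes, and part of this may be signal that any immunoprecipitation collects at strongly transcribed genes. That explanation needs tRNA genes to be marked as well. Of them 20.3% had a summit nearby, against 4.62% at random, but 19.97% of all protein-coding genes were bound too. Random placement does not allow for summits lying near start sites in general, so this test cannot show tRNA genes to be specially marked. The snRNA (9.38%) and snoRNA genes (9.29%) did not differ from random placement past the threshold. For rRNA genes (0 of 99) the test could not have called fewer summits than at random. Together these values decide nothing. Signal at genes that most cells use, whatever their function, stays open, since 4 of 7 such lists were enriched and 3 were not. More start sites per gene are not the whole cause, since 9 of the 10 enriched lists passed with 1 start site per gene, but the odds ratio fell from 7.4 to 3.32 for ecdysone response, from 10.1 to 6.32 for stress and redox and from 7.23 to 4.73 for phospholipid synthesis. General signal at transcribed genes stays open, since expression in these animals and a GFP control were not analysed here.

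The strong peaks within Ctps could come from extra DNA copies brought by the transgene or from binding. Copies of the whole gene, acting alone, would raise the exons at its 3′ end as well. The strongest pooled signal there was 57.0, against at least 1043 in the group, which argues against whole-gene copies as the only source. Whole-gene copies together with binding are not excluded, and the criterion was set after these values were seen. The lists were called against a control alignment, which would offset copies if it came from the same flies, but its source is unknown here. Copies of an upstream fragment therefore cannot be told apart from binding. Peaks covered 72.2% of the stretch, against at most 39.8% in any other window of its length. The covered regions had 49.5 to 54.1% GC and the gaps between them 27.0 to 33.1%. The gaps thus go with base content and alone do not show separate binding sites. A further hypothesis was that CG45071, which shares the name CG6854, encodes a DNA-binding protein of the MADF family that binds its own start. Its protein had 0 blastp hits to the family, while 6 of 8 known members found another at the same threshold and 2 did not, so the search gave no support and does not exclude a distant member.

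GA-rich sequence at summits could reflect the base content of promoters. Against unbound start sites at the same distance, however, GAGA had an odds ratio of 4.72 in promoter peaks (Fisher's exact test, adjusted p = 8.55e-25; 7.0% against 1.57%). This argues against the content of promoters in general as the whole cause. The unbound start sites were not matched for base content, so a difference in base content between bound and unbound promoters stays open. Whether the tagged protein or another factor at these sites recognises the repeats was not tested.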
